A study of Mus musculus with 5 samples.

How the data were processed

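The data are 5 single-cell libraries from female C57BL/6 mice of 6 to 8 weeks, 1 library per group: laminectomy at 0 dpi, and saline or NP at 2 and at 7 dpi after a C5 lateral hemisection with a bridge implant. Per the labels, NP were given as 1 mg in 0.1 mL within 2 h of injury and then every 24 h, cord from C4 to C6 was dissociated with removal of myelin on beads, and cells of 3 to 4 mice were pooled before fixation. Per the labels, the assay was 10x Flex, in which pairs of probes from the mouse probe set v1.0.1 are hybridised to fixed RNA, sequenced on a NovaSeq X. The deposited values are counts: per the file headers each matrix holds whole numbers, the UMI counts of 19059 genes per cell barcode, from Cell Ranger 7.2.0. The submitters' processing notes list Cell Ranger 9.0.1 as well, without its role, and name the builds GRCm38 and mm10. No normalization had been applied to the deposited counts, and the lowest total of any barcode was 493 UMIs, so the barcodes are the cells the authors' pipeline called. Gene positions were taken from GENCODE release vM21 by gene identifier.

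The barcodes of the laminectomy library carried 1 probe barcode and those of each injured library 2. The labels do not explain these, so they were not taken as replicates; values in each probe barcode subset were used only as a technical check. Between 34.9% and 48.1% of the droplet barcodes of the smaller library of a pair were shared with the other, and the labels do not say which libraries were loaded together, so library, loading and group cannot be told apart.

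Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were marked per library with Scrublet as called from scanpy 1.11.5 (expected rate 0.08, automatic threshold). In saline at 2 dpi the automatic threshold marked 0 cells, and 0.25 was used there, as laid down for a library where under 0.5% are marked. Doublets removed were 13.9% (laminectomy), 3.36% and 3.51% (saline and NP at 2 dpi), and 7.79% and 6.19% (saline and NP at 7 dpi). Counts were scaled to 10000 per cell and log1p transformed. Variable genes (2000), principal components (30), nearest neighbours (15) and Leiden clustering at resolution 1 with seed 1 followed, in scanpy with igraph 0.11.9 and scikit-learn 1.9.0. Libraries were not integrated, since library and group coincide. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, used only for TMM factors.

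Clusters were named from 22 marker lists. The candidate class of a cluster was that with the highest mean standardised marker level. The cluster took this name if it had at least 100 cells, if at least 3 of the markers were detected in 10% or more of its cells, and if no other class had more markers among its 10 leading genes by fold against all other cells, at 100 CPM or more. A cluster whose median depth lay below the library median divided by 3 also needed a marker of its own among those genes. Clusters whose profile correlated at 0.97 or more with the rest of their library were set aside as whole-library profiles; this threshold and the limits of the naming rule were set after the clusters were seen. Of 58 clusters, 33 were named into 16 classes, 18 stayed unnamed and 7 were set aside. The set-aside cells at 2 dpi were mostly cluster c16, which held 9.21% of saline and 22.2% of NP cells. Unnamed clusters held 11.8%, 11.2%, 10.2%, 8.72% and 6.72% of cells in the order laminectomy, saline and NP at 2 dpi, saline and NP at 7 dpi. The largest unnamed clusters, c2 with 9206 cells and c4 with 4149, scored highest for endothelial markers. Comparing leading genes with other classes instead of all other cells was tried first and is kept as an alternative; it names c2, c4 and c43. Monocyte-macrophage and border macrophage clusters were joined, as were oligodendrocyte and precursor clusters, after the clusters were seen.

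With 1 library per group there is no test across animals and no p-value. The share of a class among kept cells is given with its exact Clopper-Pearson 95% interval, and a ratio of shares with an exact conditional binomial interval. UMIs were summed over the cells of a class in each library and expressed as CPM, scaled to the total of that sum. A fold is the ratio of CPM with an exact conditional binomial 95% interval. A list value is the median, over members with at least 20 UMIs in both sums together and 10 CPM in at least 1 of them, of the log2 ratio after adding 5 CPM to each side. It has a 95% interval from 1000 Poisson redraws and a percentile among 10000 random lists of equal size matched on expression; members at least 1.5-fold apart are counted to describe size. Classes with under 100 cells in either library got no list value. All intervals cover counting error only and leave out differences between animals and between libraries.

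The comparisons were NP with saline at 2 and at 7 dpi, saline at 2 and at 7 dpi with laminectomy, and 7 with 2 dpi in saline and in NP. The markers, the 27 gene lists, the comparisons, the filters and the rule for named genes were fixed before the data were examined. The rule takes, in each NP comparison, the 3 highest and 3 lowest genes by log2 ratio with 5 CPM added, in microglia-like, monocyte/macrophage-like, neutrophil-like, astrocyte-like and endothelial-like cells, and in the other comparisons in microglia-like, monocyte/macrophage-like and astrocyte-like cells. Genes needed at least 50 CPM and 50 UMIs in at least 1 of the sums, and markers of any other class were left out. From each list described by its genes the 2 highest and the 2 lowest members are given, except for a few genes whose results are not reported here. Which of the 494 list values are described was chosen after they were seen. C1qa in astrocyte-like cells was chosen after its values were seen.

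The alternatives tried were at least 500 genes per cell, doublets kept, Leiden resolutions 0.5 and 2, a class for each cell from its marker score, shares of leukocytes only, cells thinned to 1000 UMIs, TMM factors, the mean of the cells' own CPM, a pseudocount of 1 CPM, no filter on low members, and members at 50 CPM or more. Added after the data were seen were the other naming fold, a correlation threshold of 0.95 or none, shares outside the set-aside clusters, and the largest cluster of a class alone. Thinning left out 4.26%, 13.3%, 17.5%, 2.19% and 2.04% of cells in the library order above, those with under 1000 UMIs.

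The calculations were tested on simulated data made from the microglia-like sums of NP and saline at 2 dpi. Over 8740 genes with 50 each changed 2-fold up, 2-fold down, 1.5-fold up and 1.5-fold down, the 95% intervals held the true value for 96%, 96%, 96% and 94% of changed genes and for 95.3% of 8481 unchanged ones. A list of 20 genes changed 2-fold reached percentile 100. Lists of 20 unchanged genes, first 20 lists and then 100, had a median percentile of 44.8 over the 100. Raw reads were not used here, and no label gives single animals, so pooled mice were not separated. Neuron-like, mast cell and platelet classes were not compared for genes, having under 100 cells in the injured libraries or no named cluster.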

Results

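Gene expression was measured cell by cell in mouse spinal cord, with and without injury, and after injury with saline or with nanoparticles (NP), to ask how inflammation develops and how the particles change it. The injured cords had a lateral hemisection at C5 with a bridge implanted, and they were taken 2 or 7 days post injury (dpi) from mice given saline or NP. A laminectomy library, sampled at 0 dpi, was the reference without injury. By their titles the injured libraries were of spinal cord and bridge implant, and the laminectomy library was of spinal cord alone. There were 5 groups, each with 1 library of cells pooled from 3 to 4 mice, so no value has a replicate, no test across animals was possible, and every interval below covers counting error only. What the particles are made of is not stated in the labels. The labels call the bridge PCL and the series description calls it PLG, and they describe the reference animals both as laminectomised and as naive.

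The libraries held 37037 barcodes and 256256598 UMIs (laminectomy), 24289 and 148337321 (saline 2 dpi), 30061 and 155573287 (NP 2 dpi), 38691 and 498876644 (saline 7 dpi), and 34616 and 471272418 (NP 7 dpi). The median number of UMIs per barcode was 4752, 3083, 2609, 8789 and 9558 in the same order. After filtering, 31772, 23027, 28697, 35384 and 32298 cells were kept. They formed 58 clusters, called c0 to c57, of which 33 received the name of a marker class; a class is called by that name plus "-like", since it rests on marker genes alone. Of the remaining clusters, 18 had no clear class, and 7 had a profile that resembled the average of their own library and were set aside. These 7 clusters held 15.5% of cells in the laminectomy library, 11.4% and 22.7% in saline and NP at 2 dpi, and 5.30% and 8.20% in saline and NP at 7 dpi.

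The main question was what NP changed against saline. Among myeloid cells at 2 dpi, inflammatory cytokine genes were higher with NP, and interferon response genes were lower in the microglia-like and monocyte/macrophage-like classes. Over the whole class, neutrophil-like cells had higher inflammatory, chemokine, activation and hypoxia genes and lower granule genes. In their main cluster alone, c30, the granule median was 0.09 and the inflammatory, chemokine and activation medians were 0.28, 0.19 and 0.34. Shares of the main myeloid classes were close. Microglia-like cells made up 10.6% of NP cells and 11.3% of saline cells, a ratio of 0.934 [0.886, 0.984], monocyte/macrophage-like cells 15.8% and 17.2%, a ratio of 0.923 [0.885, 0.964]. Neutrophil-like cells made up 17.7% and 17.0%, a ratio of 1.04 [0.996, 1.08]. Several smaller classes were less frequent with NP, among them B cell-like cells with a ratio of 0.323 [0.272, 0.383], oligodendrocyte-lineage-like cells with 0.342 [0.288, 0.404], fibroblast-like cells with 0.357 [0.292, 0.434], and T or NK cell-like cells with 0.470 [0.365, 0.602]. Erythroid-like cells had a ratio of 0.491. Unnamed c38, led by Krt5 and Krt14, held 163 saline and 10 NP cells, and c27, led by Ctsg and Elane, 53 and 0. Also mostly of saline were unnamed c17 (80 and 1), c18 (26 and 0), c39 (24 and 0), c55 (92 and 0) and c56 (89 and 4). Unnamed c29 (0 and 41) and c57 (1 and 64) went the other way. With 1 library per group, an NP effect and a difference in the tissue taken cannot be told apart. The oligodendrocyte-lineage-like ratio is uncertain: shares in the probe barcode subsets were 1.27% and 2.65% in saline and 1.32% and 0.222% in NP. It was 0.22 with a correlation limit of 0.95 for clusters set aside and 0.141 to 0.753 over all alternatives. Outside the clusters set aside, which held 1.99 times the share in NP, the ratios of microglia-like and monocyte/macrophage-like cells reversed to 1.07 and 1.06. Among leukocyte-like cells the microglia-like ratio was 1.01, and with a class for each cell from its markers the monocyte/macrophage-like ratio was 1.17.

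**Figure D1:**
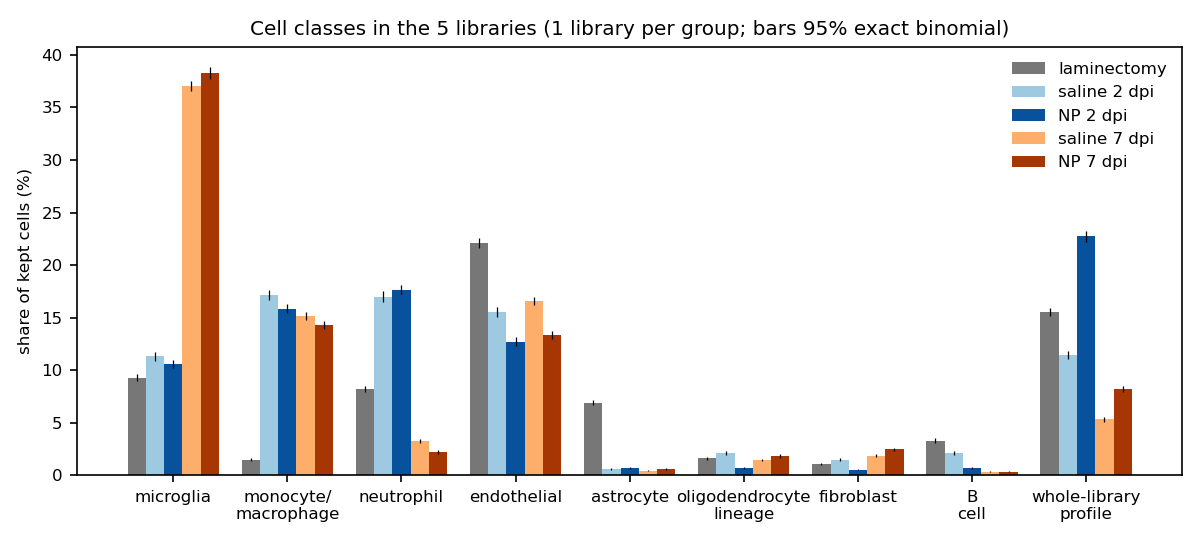
Share of kept cells in each cell class (percent, y axis) for the 5 libraries, with exact 95% Clopper-Pearson intervals as error bars (counting error only, 1 library per group). Microglia-like cells went from 9.26% in the laminectomy library to 37.0% and 38.3% at 7 dpi, and neutrophil-like cells peaked at 17.0% and 17.7% at 2 dpi.

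In microglia-like cells at 2 dpi, 77.9% (saline) and 82.8% (NP) of which were in cluster c46, whose leading genes include the cell cycle genes Mki67 and Top2a, the inflammatory list had a median log2 ratio of 0.32 [0.29, 0.35] over 13 measured members, above all 10000 matched random lists. Its members ran from Osm, a cytokine of the IL-6 family, at 1.07-fold and Nlrp3, the inflammasome sensor, at 1.12-fold to Ptgs2, the inducible cyclooxygenase, at 1.46-fold and Tnfaip3, an NF-kB feedback inhibitor, at 1.55-fold. The interferon list lay at -0.64 [-0.71, -0.56] over 18 members, below all random lists, with 9 members at least 1.5-fold lower and none higher by that much. Oasl2 at 0.341-fold and Ifi27l2a at 0.369-fold [0.353, 0.385] were its lowest members, and Stat2 at 0.817-fold and Ifih1, a sensor of viral RNA, at 0.866-fold its highest. By the size rule the highest genes were Tnfsf9, the ligand of the costimulatory receptor 4-1BB, at 2.13-fold [2.02, 2.24] (149 against 69.9 CPM, counts scaled to a fixed total), Ly6a at 1.57-fold [1.46, 1.70] and Tnfaip3. The lowest were Ifi27l2a, Ifitm3, an interferon-induced antiviral membrane protein, at 0.474-fold [0.449, 0.500], and Calm2, a calmodulin gene, at 0.602-fold, whose log2 ratio varied from -1.61 to 0.07 between probe barcode subsets of the libraries. Homeostatic genes (-0.03), lipid handling genes (-0.07), proliferation genes (0.02) and hypoxia genes (-0.03) had medians near 0, and no measured member of these 4 lists differed by 1.5-fold.

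Monocyte/macrophage-like cells at 2 dpi were mostly of cluster c35 (68.0% in saline, 76.5% in NP), followed by c36 (22.8% and 15.3%). Their inflammatory list had a median of 0.55 [0.53, 0.57] over 17 members, above all random lists, with 8 members at least 1.5-fold higher and none lower. Nos2, the inducible nitric oxide synthase, was highest at 3.98-fold [3.69, 4.28] (86.8 against 21.8 CPM), then Ptges, a prostaglandin E synthase, at 2.85-fold. Icam1 at 1.07-fold and Tnfaip2 at 1.10-fold were lowest. The hypoxia and glycolysis list stood at 0.29 [0.27, 0.32], from Hif1a at 0.95-fold and Pkm at 1.11-fold to Ero1l at 1.86-fold and Egln3, an oxygen-sensing prolyl hydroxylase, at 2.25-fold. Interferon genes had a median of -0.48 [-0.50, -0.42] with 4 of 20 members at least 1.5-fold lower; Irf7, the interferon-inducible transcription factor, at 0.555-fold and Isg15 at 0.583-fold were lowest and Trim30a at 0.861-fold was among the highest. In c35 alone the median was -0.18 and no member passed 1.5-fold. The pro-repair list (-0.11) and the scavenger receptor list (-0.13) were slightly lower, the former reading 0.03 in c35 alone. Pro-repair members ran from Retnla at 0.0732-fold and Mrc1, the mannose receptor, at 0.400-fold [0.388, 0.413] to Arg1, arginase, at 1.39-fold and Vegfa at 1.78-fold. Scavenger members ran from Mrc1 and Cd163, the haemoglobin-haptoglobin receptor, at 0.408-fold [0.387, 0.430] to Clec4n at 1.28-fold and Olr1 at 1.42-fold. By the size rule, Tnfrsf9, the 4-1BB receptor, was highest at 4.16-fold [3.84, 4.51], followed by Nos2 and Slc7a2, an arginine transporter, at 2.59-fold [2.44, 2.75]. Tppp3 at 0.282-fold [0.270, 0.293], Mrc1 and Cd163 were lowest. Unnamed c55, with Lyve1, Cd163 and Mrc1 among its leading genes, held 92 saline and 0 NP cells and is not part of this class.

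Neutrophil-like cells at 2 dpi were mostly of cluster c30 (79.9% of the class in saline, 93.2% in NP), while the clusters led by granule genes, c26 and c28, held 241 and 547 saline cells against 56 and 286 NP cells. Cells of c26 had a median depth of 4.36 relative to their library median, so they weigh more in the sums than their number. At Leiden resolution 0.5 and after thinning, the cluster led by Mpo and Elane stayed unnamed, with mast cell as its candidate class. List medians were not computed under those namings. Over the whole class the inflammatory list had a median of 0.88 [0.75, 0.89], with 15 of 17 members at least 1.5-fold higher, from Osm at 0.840-fold and Il1b at 1.44-fold to Il1a at 3.42-fold and Il23a, a subunit of interleukin 23, at 4.07-fold [3.74, 4.43]. The ageing and activation list stood at 1.00 [0.99, 1.01], with Cxcr2 at 0.984-fold among its lowest members and Icam1 at 2.78-fold and Cd274, the checkpoint ligand PD-L1, at 3.06-fold its highest. Chemokine genes had a median of 0.86 [0.83, 0.90], from Ccl6 at 0.689-fold and Ccl7 at 0.850-fold to Cxcl3 at 3.8-fold and Cxcl10 at 4.02-fold. Hypoxia and glycolysis genes had 0.99 [0.93, 1.08], from Slc2a3 at 0.810-fold and Hif1a at 1.24-fold to Ero1l at 3.65-fold and Egln3 at 3.66-fold. The granule and maturation list was at -0.72 [-0.77, -0.68], with 11 of 16 members at least 1.5-fold lower, from Mpo, myeloperoxidase, at 0.106-fold [0.102, 0.109] and Elane, neutrophil elastase, at 0.164-fold to Itgam at 1.19-fold and Mmp9 at 1.35-fold. Interferon genes stood at 0.17, from Trim30a at 0.891-fold and Ifi27l2a at 0.913-fold to Usp18 at 1.45-fold and Rsad2 at 1.47-fold. Within c30 alone the medians were 0.28 (inflammatory), 0.34 (activation), 0.19 (chemokine), 1.04 (hypoxia), 0.09 (granule) and -0.19 (interferon), so the granule and interferon medians changed sign and the hypoxia median stayed near its value over the class. The immediate early and stress list was at 0.37 over the class and -0.09 in c30. With each cell counted alike, the class medians were 0.44 (inflammatory), 0.47 (chemokine), 0.54 (activation) and -0.09 (interferon). By the size rule, Hspa1a, a stress-induced chaperone, was highest at 6.57-fold [5.39, 8.06], followed by Il23a and Cxcl3 [3.59, 4.02]. Prg2, an eosinophil granule protein, at 0.00402-fold (7 against 1878 UMIs, with log2 ratios from -5.90 to 0.12 between probe barcode subsets and 0.06 with a class for each cell from its markers), Ctsg, cathepsin G, at 0.0930-fold [0.0869, 0.0994] and Mpo were lowest.

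Endothelial-like cells were 12.7% of NP cells and 15.5% of saline cells at 2 dpi, a ratio of 0.820 [0.782, 0.858], and 5.26% of the class in NP against 24.9% in saline lay in cluster c3, which is led by Plvap, Gpihbp1, Fabp4 and Aqp1. The size rule gave Fabp4, a fatty acid binding protein, at 0.0413-fold [0.0389, 0.0437], Aqp1, a water channel, at 0.0482-fold, and Cd36, a fatty acid receptor, at 0.0764-fold as the lowest genes. In c0 and c1 alone they were at 0.117-fold, 0.0222-fold [0.00712, 0.0529] and 0.535-fold. Ccn2, a matricellular growth factor, at 1.57-fold [1.52, 1.62], Dbp, a circadian transcription factor, at 1.53-fold, and Tsc22d3, a glucocorticoid-induced leucine zipper protein, at 1.48-fold were highest. Proliferation genes had a median of -0.42 [-0.48, -0.34] with 6 of 20 members at least 1.5-fold lower, from Ccnb2 at 0.475-fold and Ccna2 at 0.518-fold to Mcm5 at 1.04-fold and Mcm2 at 1.18-fold. Clusters c2 and c4, which carried endothelial markers without meeting the naming rule, held 4.94% and 3.93% of saline cells against 5.57% and 4.23% of NP cells. These shares went the other way, and the clusters set aside held 11.4% of saline and 22.7% of NP cells. The lower endothelial-like share thus depends in part on the naming rule and on the clusters set aside.

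Astrocyte-like cells numbered 132 in saline and 189 in NP at 2 dpi, of which 3.03% and 9.52% lay in c45, a cluster that scored nearly as high for endothelial as for astrocyte markers. Their pan-reactive list had a median of 0.58 [0.28, 0.74] over 15 members, from Nes at 0.611-fold and Aspg at 0.873-fold to Timp1, a metalloproteinase inhibitor, at 3.50-fold and Cp, ceruloplasmin, at 8.99-fold. The homeostatic list was at -0.52 [-0.60, -0.48], from Gjb6 at 0.541-fold and Slc6a11, a GABA transporter, at 0.562-fold to Slc1a3 at 0.821-fold and Aldh1l1 at 0.97-fold. The genes named by size rested on few molecules: Ccl5 was at 51.2-fold [8.87, 2050.2] from 67 against 1 UMIs, Atp10a at 13.3-fold and Ace, angiotensin-converting enzyme, at 14.8-fold [4.81, 73.7], while Syt4 was at 0.00549-fold [0.000138, 0.0311], Ifit3 at 0.0630-fold and Lgals3, galectin 3, at 0.0716-fold. Ccl5, Syt4 and Ifit3 changed direction between probe barcode subsets, and C1qa, a microglial complement gene, was at 129 CPM in these NP cells against 592 in saline. In fibroblast-like cells the fibrosis and matrix list had a median of -0.19, with 9 of 23 members at least 1.5-fold lower and 4 higher, from Acta2 at 0.126-fold and Postn, periostin, at 0.128-fold to Timp1 at 1.91-fold and Fn1, fibronectin, at 2.12-fold. In pericyte-like cells it was at -0.18, from Postn at 0.0502-fold and Col12a1 at 0.122-fold to Col1a2 at 1.34-fold and Tgfbi at 2.29-fold, and with a class for each cell from its markers at 0.57; c32 held 35.6% of this class in saline and 24.4% in NP. With such classes the astrocyte-like medians were 0.33 (pan-reactive) and -0.18 (homeostatic).

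**Figure D2:**
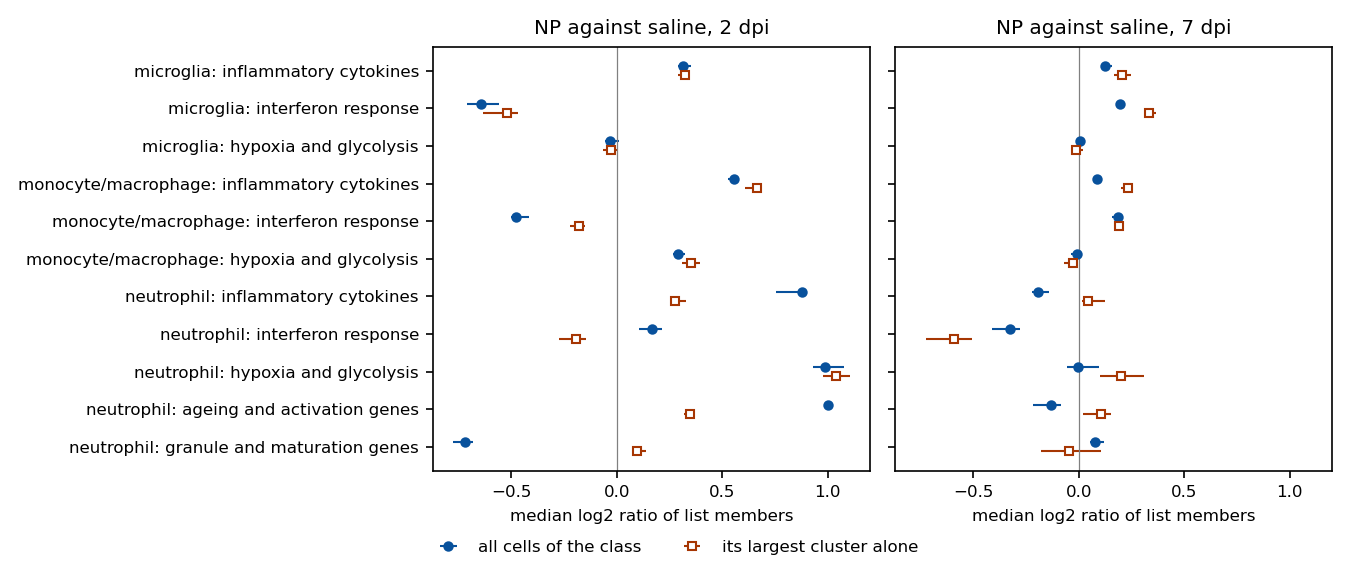
Median log2 ratio of NP over saline (x axis) of gene lists in 3 myeloid classes (y axis) at 2 dpi and 7 dpi, over all cells of the class (filled circles) and in its largest cluster alone (open squares), with 95% intervals from Poisson redraws as error bars (counting error only). Over all neutrophil-like cells the inflammatory list lay at 0.88 at 2 dpi and -0.19 at 7 dpi, and in c30 alone at 0.28 and 0.04.

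With NP at 7 dpi, the inflammatory medians of the 3 myeloid classes were closer to 0 than at 2 dpi, and the interferon list was above 0 in microglia-like and monocyte/macrophage-like cells and below 0 in neutrophil-like cells. Neutrophil-like cells were less frequent with NP, at 2.19% against 3.23%, a ratio of 0.679 [0.617, 0.746]. Microglia-like cells were 38.3% against 37.0% (ratio 1.03 [1.01, 1.06]) and monocyte/macrophage-like cells 14.3% against 15.1% (ratio 0.947 [0.910, 0.985]), but in NP these shares were 35.9% and 40.3%, and 15.5% and 13.3%, in the probe barcode subsets. Endothelial-like cells were less frequent (ratio 0.807 [0.776, 0.840]), and fibroblast-like cells (1.31 [1.18, 1.45]), smooth muscle-like cells (1.33 [1.22, 1.46]) and astrocyte-like cells (1.37 [1.09, 1.72]) were more frequent. Schwann cell-like cells had a ratio of 2.09 [1.75, 2.50], the highest among classes with at least 100 cells in each library. In NP the shares of these classes differed between the probe barcode subsets: 0.733% and 1.46% (Schwann cell-like), 0.420% and 0.677% (astrocyte-like, with 0.408% and 0.406% in saline), and 3.82% and 2.98% (smooth muscle-like, with 2.20% and 2.92% in saline). The NP effect at 7 dpi minus that at 2 dpi, on the log2 scale, was -1.07 for the inflammatory list in neutrophil-like cells, 0.84 for the interferon list in microglia-like cells and 0.66 in monocyte/macrophage-like cells; these differences were not tested.

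Microglia-like cells at 7 dpi were spread alike over clusters c12 (38.2% in saline, 40.6% in NP), c8 (24.5% and 22.7%) and c11 (18.9% and 17.2%). The interferon list had a median of 0.20 [0.18, 0.22], from Rsad2, the antiviral enzyme viperin, at 0.971-fold and Ifit3 at 1.02-fold to Oasl2 at 1.33-fold and Ifi27l2a at 1.44-fold [1.41, 1.46]. The inflammatory list stood at 0.13 [0.12, 0.16], from Cd14 at 1.02-fold and Il1a at 1.03-fold to Tnf at 1.29-fold and Ptgs2 at 1.36-fold. Homeostatic (-0.03), lipid handling (0.03), proliferation (0.04) and hypoxia (0.01) lists were near 0, the homeostatic and proliferation medians reading 0.03 and -0.05 in c12 alone. Over the class no member of any of these 6 lists differed by 1.5-fold. In c12 alone the interferon median was 0.33 [0.31, 0.37], with 1 member at least 1.5-fold higher, and the inflammatory median was 0.21 [0.17, 0.25]. Cxcl2, a neutrophil-attracting chemokine, at 1.52-fold [1.49, 1.55], Saa3, an acute-phase protein, at 1.51-fold [1.47, 1.54] and Ifi27l2a were highest by size. Serf2 at 0.682-fold (log2 ratios from -1.62 to 0.03 between subsets), Cd5l, a macrophage scavenger protein, at 0.770-fold [0.762, 0.779] and Gng2 at 0.806-fold were lowest.

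In monocyte/macrophage-like cells at 7 dpi, with c34 (48.9% in saline, 51.5% in NP) and c37 (28.2% and 26.9%) as the main clusters, the interferon list had a median of 0.19 [0.16, 0.20], from Oasl1 at 0.906-fold and Ifit1 at 0.924-fold to Rsad2 at 1.26-fold and Ifi27l2a at 1.5-fold. The inflammatory list was at 0.09 [0.07, 0.10], from Tlr2 and Tnf, both at 1.01-fold, to Nlrp3 at 1.16-fold and Cd14 at 1.18-fold, and the scavenger receptor list at 0.12, from Olr1 at 0.864-fold and Cxcl16 at 0.988-fold to Cd5l at 1.34-fold and Cd163 at 1.65-fold. The hypoxia (-0.01) and pro-repair (0.03) lists were near 0. With each cell counted alike, the interferon, inflammatory and pro-repair medians were -0.01, -0.09 and -0.03. In c34 alone the inflammatory median was 0.23 [0.20, 0.26]. Mmp13, a collagenase, was highest by size at 1.90-fold [1.84, 1.96], then Ace at 1.74-fold [1.67, 1.82] and Dusp1, a phosphatase of MAP kinases, at 1.52-fold. Ccl24, an eosinophil-attracting chemokine, at 0.551-fold [0.534, 0.569], Serf2 at 0.634-fold, again varying between subsets (-1.75 to 0.04), and Fn1 at 0.727-fold were lowest.

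In neutrophil-like cells at 7 dpi, 66.7% (saline) and 61.6% (NP) of which were in c30, the interferon list was lower, at -0.33 [-0.41, -0.28], with 7 of 20 members at least 1.5-fold lower and 1 higher; in c30 alone it was at -0.59. It ran from Rsad2 at 0.340-fold [0.316, 0.366] and Ifit1 at 0.341-fold to Zbp1 at 1.34-fold and Ifi27l2a at 1.73-fold. The inflammatory list was at -0.19 [-0.22, -0.14], from Tnfaip2 at 0.647-fold and Ptgs2 at 0.768-fold to Cd14 at 0.991-fold and Il23a at 1.27-fold. The chemokine list was at -0.21, with Ccl5 detected at 18.5 CPM in saline and at 0 in NP, then Cxcl10, an interferon-induced T cell attractant, at 0.206-fold [0.169, 0.25], up to Ccl9 at 1.88-fold and Cxcl12 at 2.13-fold. Activation (-0.13), granule (0.08) and hypoxia (-0.00) lists were close to 0. In c30 alone the inflammatory, activation and granule medians were 0.04, 0.10 and -0.05, and the hypoxia median was 0.20 [0.10, 0.31]. S100a4 at 4.88-fold [4.18, 5.72], Crip1 at 4.50-fold and S100a10 at 4.34-fold were highest by size, and Cxcl10, Rsad2 and Ifit1 lowest. With 1143 saline and 708 NP cells, several of these medians changed sign between probe barcode subsets, the inflammatory one from -0.42 to 0.08.

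In endothelial-like cells at 7 dpi proliferation genes were higher, with a median of 0.65 [0.54, 0.73] and 8 of 15 members at least 1.5-fold higher, from Mcm3 at 0.988-fold and Mcm6 at 1.09-fold to Mki67 at 2.19-fold and Top2a, a topoisomerase of dividing cells, at 2.51-fold; with each cell counted alike the median was -0.02. Fabp4 at 6.70-fold [6.35, 7.06], Cd36 at 4.66-fold and Aqp1 at 2.81-fold were the highest genes, again with more of the class in c3, 8.28% against 3.96%. Ivns1abp at 0.617-fold, Lrrn3 at 0.656-fold and Hspa1a at 0.671-fold were lowest. Astrocyte-like cells (144 in saline, 180 in NP) had a pan-reactive median of -1.40 [-1.64, -1.29], with 14 of 16 members at least 1.5-fold lower, from Cxcl10 at 0.0248-fold [0.00294, 0.0926] and Timp1 at 0.120-fold to Serpina3n at 0.708-fold and Stat3 at 0.710-fold, and it was below 0 in each comparison of probe barcode subsets (-1.79 to -0.88). The immediate early and stress list, a sign of handling, was lower as well, at -0.74. Their homeostatic list was at 0.48, from Aqp4, the astrocyte water channel, at 0.951-fold and Aldh1l1 at 1.22-fold to Gjb6 at 1.58-fold and Slc1a3, a glutamate transporter, at 2.25-fold, with subsets from -0.08 to 0.97. C1qa was at 1211 CPM in these NP cells and 1807 in saline. Hes5, a Notch target, at 17.0-fold [5.53, 85.0], Apod at 6.23-fold and Gabbr2 at 5.57-fold were highest by size, and Ccn5 at 0.0132-fold [0.0027, 0.0391], Mmp12, a macrophage elastase, at 0.0556-fold and Cxcl10 lowest. The fibrosis and matrix list had a median of 0.18 [0.17, 0.19] in fibroblast-like cells, from Tgfb1 at 0.870-fold to Loxl2 at 1.39-fold and Postn at 1.58-fold. In pericyte-like cells it was at 0.39 [0.35, 0.42], with subsets from -0.19 to 1.00 and 22.5% (saline) and 30.5% (NP) of the class in c32. Ccn1 at 0.887-fold and Tgfb1 at 0.975-fold were lowest and Timp1 at 2.22-fold was among the highest.

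The saline libraries against laminectomy compare injured cord with its bridge implant, without NP, with uninjured cord alone. The tissue taken thus differed by the implant as well as by injury. With 1 library each, injury cannot be told apart from this difference or from others between the libraries. Erythroid-like cells were 2.68% of laminectomy cells against 0.347% and 0.246% in saline at 2 and 7 dpi. Cluster c26, led by Mpo, Elane and Prtn3, held 838 laminectomy cells against 241 and 32. Lower shares of such cells in saline are thus not shown to be an effect of injury. Monocyte/macrophage-like cells went from 1.46% to 17.2% at 2 dpi (ratio 11.8 [10.7, 13]) and 15.1% at 7 dpi (10.4 [9.43, 11.4]), and microglia-like cells from 9.26% to 11.3% (1.22 [1.16, 1.29]) and then 37.0% (4.00 [3.84, 4.17]). Neutrophil-like cells went from 8.20% to 17.0% (2.07 [1.97, 2.18]) and then to 3.23% (0.394 [0.367, 0.422]). These ratios join clusters that went different ways. Cluster c30 held 0.390% of laminectomy cells and 13.6% and 2.15% of saline cells at 2 and 7 dpi. The granule-gene cluster c28 held 5.17%, 2.38% and 0.986% in the same order. Astrocyte-like cells were 6.90%, 0.573% and 0.407% of cells in the 3 libraries, and B cell-like cells 3.28%, 2.07% and 0.294%. Neuron-like cells numbered 201 in the laminectomy library and 1 in each saline library. They formed c50, led by Prph, Nefl, Tubb3 and Fxyd2. Whether they came from the cord itself was not tested, so the difference is not a measure of neurons lost to injury. Among leukocyte-like cells alone, the ratios at 2 and 7 dpi were 0.572 and 1.61 for microglia-like, 5.51 and 4.18 for monocyte/macrophage-like, and 0.97 and 0.159 for neutrophil-like cells. Laminectomy neutrophil-like cells were mostly in the granule-gene clusters c28 (63.1%) and c26 (32.2%), and laminectomy monocyte/macrophage-like cells in c36 (54.2%) and c34 (45.6%), with none in c35.

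After injury, microglia-like cells had lower homeostatic and higher lipid handling transcripts. The class lay in other clusters than before, with 63.4% in c8 in the laminectomy library, 77.9% in c46 at 2 dpi and 38.2% in c12 at 7 dpi, against 0.238% in c12 in laminectomy. The homeostatic list had medians of -1.05 [-1.07, -1.04] at 2 dpi and -1.24 [-1.26, -1.23] at 7 dpi, with 11 and 12 of 14 members at least 1.5-fold lower. Slc2a5, a fructose transporter, was at 0.248-fold and 0.177-fold and P2ry12, the microglial purine receptor, at 0.271-fold and 0.275-fold, while Fcrls (1.65-fold and 1.69-fold) was highest, followed at 2 dpi by Golm1 (0.964-fold). The lipid handling and phagocytic list had medians of 1.39 [1.36, 1.45] and 2.49 [2.46, 2.53], and the proliferation list 3.44 [3.37, 3.59] and 1.46 [1.36, 1.55]. The interferon list stood at 0.89 and 1.16 and the immediate early and stress list at -1.74 and -1.41. At 7 dpi the homeostatic and stress medians were -0.70 and -0.86 with TMM factors, and the proliferation median was 0.80 with members at 50 CPM or more. Spp1, osteopontin, was 161-fold [153, 170] higher at 2 dpi (15348 against 95.3 CPM) with Msr1, a scavenger receptor, at 221-fold and Ch25h, cholesterol 25-hydroxylase, at 94.7-fold. At 7 dpi the highest genes were Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, at 252-fold [212, 301], Spp1 at 124-fold and Cd5l at 513-fold. Hspa1b (0.0204-fold and 0.0284-fold), Hspa1a (0.0616-fold and 0.0584-fold) and Gpr165 (0.0548-fold and 0.0332-fold) were lowest at both times. The share of microglia-like cells with a UMI of Mki67 or Top2a was 4.96% in the laminectomy library, 54.1% at 2 dpi and 12.8% at 7 dpi, against 4.84%, 6.13% and 3.81% of endothelial-like cells. After thinning to 1000 UMIs these were 1.07%, 32.0% and 3.20% against 0.984%, 2.67% and 0.581%. Other thinned shares were 26.3%, 5.66% and 3.65% in neutrophil-like cells, 4.22%, 2.29% and 5.35% in monocyte/macrophage-like cells, and 26.3%, 29.97% and 9.56% in the clusters set aside.

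**Figure D3:**
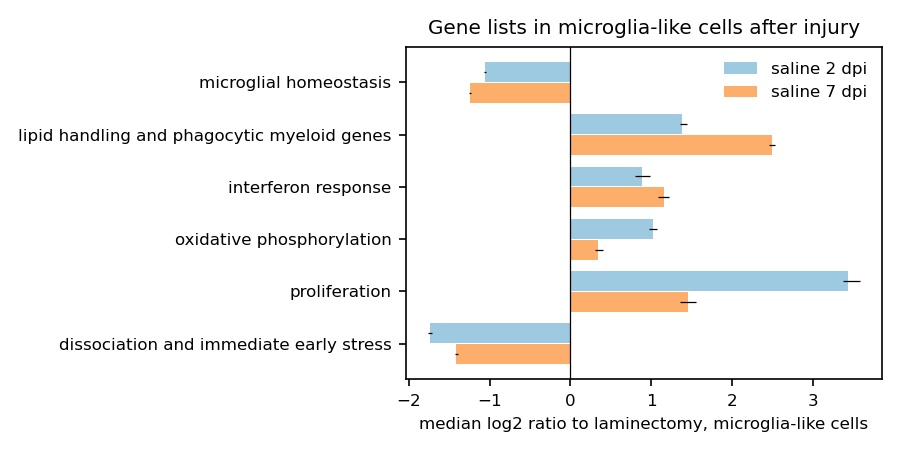
Median log2 ratio over laminectomy (x axis) of gene lists (y axis) in microglia-like cells in saline at 2 and 7 dpi, with 95% intervals from Poisson redraws as error bars (counting error only). The proliferation list went from 3.44 at 2 dpi to 1.46 at 7 dpi while the lipid handling list went from 1.39 to 2.49.

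Monocyte/macrophage-like cells had lipid handling medians of 1.27 and 2.40 at 2 and 7 dpi, hypoxia and glycolysis medians of 1.75 and 0.87, and MHC class II medians of -1.60 and -1.25. The class lay in c36 (54.2%) and c34 (45.6%) in laminectomy, and mostly in c35 (68.0%) in saline at 2 dpi. At 7 dpi it lay mainly in c34 (48.9%) and c37 (28.2%). Make-up of the class and a change within cells cannot be told apart for these values. The MHC class II members ran from H2-Eb1 (0.0576-fold and 0.185-fold) and H2-Aa (0.0788-fold and 0.232-fold) to Cd80 (1.34-fold and 0.919-fold) and Ctss, the protease that processes the invariant chain (2.63-fold and 3.84-fold). Arg1 was 6895-fold [1909, 56933] higher at 2 dpi, from 2 laminectomy UMIs, with Gpnmb at 289.9-fold and Saa3 at 682-fold [233, 3309]. At 7 dpi Gpnmb was at 1035-fold [763, 1442], Mmp12 at 601-fold and Arg1 at 1028-fold [285, 8488]. Ctsk, cathepsin K (0.0172-fold, but a log2 ratio of 3.34 with a class for each cell from its markers), Mt3 (0.00865-fold) and Itgb3 (0.00639-fold) were lowest at 2 dpi, and Hspa1b (0.0184-fold), Mgl2 (0.0139-fold) and Hspa1a (0.0295-fold) at 7 dpi. The astrocyte-like class had a pan-reactive median of 1.97 and 2.31 and a complement median of 2.94 and 3.10, and among its highest genes were Vgf at 11427-fold [3900.1, 55494] and Syt4 at 1413-fold [474, 6936] at 2 dpi and the myeloid transcripts Spp1 at 204-fold, Gpnmb at 157-fold and Mmp12 at 238-fold at 7 dpi. C1qa was at 592 and 1807 CPM in these cells at 2 and 7 dpi against 53.0 CPM in the laminectomy library. Hspa1a at 0.0416-fold [0.00503, 0.150], Lrrn3 and Gkn3 (both 0 UMIs) were lowest at 2 dpi, where c45, led by Lrrn3 among others, held 4 cells of the class against 243 in laminectomy, and Idi1 and Mvd, enzymes of sterol synthesis, at 0.166-fold and 0.192-fold were among the lowest at 7 dpi. Values against laminectomy are relative to all genes of a class, whose median log2 ratio was -0.31 in microglia-like and monocyte/macrophage-like cells at 7 dpi and 0.17 and 0.12 with TMM factors.

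From 2 to 7 dpi, microglia-like cells had lower proliferation and higher lipid handling genes in both treatments, with c46 going from 77.9% to 4.23% of the class in saline and from 82.8% to 4.65% in NP and c12 from 1.15% to 38.2% and from 1.22% to 40.6%. Their share was 3.28 times higher at 7 dpi in saline and 3.63 times higher in NP, while neutrophil-like cells stood at 0.190 and 0.124 of their 2 dpi share. Proliferation genes of microglia-like cells had medians of -2.41 (saline) and -2.28 (NP), with all 21 measured members at least 1.5-fold lower in each, and lipid handling genes 0.61 and 0.62. In saline, Gpnmb was at 28.7-fold [27.6, 29.9], Apoc1 at 30.7-fold and Apoe, an apolipoprotein, at 16.5-fold (97524 against 5901.7 CPM), and Uhrf1, Rrm2 and Ube2c, genes of DNA replication and mitosis, at 0.100-fold, 0.111-fold and 0.117-fold. In NP, Apoc1 at 44.4-fold, Gpnmb at 35.3-fold and Apoe at 17.3-fold were highest and Hist1h1d at 0.0820-fold, Ube2c at 0.109-fold and Ccnb2 at 0.108-fold lowest. In monocyte/macrophage-like cells of saline, Mmp12 at 60.0-fold, Mfge8, a bridge to apoptotic cells, at 27.1-fold and Lpl, lipoprotein lipase, at 16.9-fold were highest, and Lcn2 at 0.0316-fold, Wfdc21 at 0.0183-fold and Chil3 at 0.0793-fold lowest. In NP these were Mmp12 at 32.2-fold, Mfge8 at 30.5-fold and Igf1, a growth factor, at 17.4-fold, and Nos2 at 0.0184-fold, Arg1 at 0.0817-fold and Saa3 at 0.0789-fold. Hypoxia and glycolysis genes of this class had medians of -0.65 in saline and -0.96 in NP, while c35 went from 68.0% to 7.73% and from 76.5% to 6.62% of the class. Astrocyte-like genes are not described for this comparison, since 132 to 189 cells per library gave values that differed widely between probe barcode subsets.

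On GRCm38, the main genes, all annotated as protein coding, lie as follows. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) and Tnfrsf9 (ENSMUSG00000028965, chromosome 4, 150914562 to 150946102) were named in monocyte/macrophage-like cells. Il23a (ENSMUSG00000025383, chromosome 10, 128296139 to 128298752) and Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413) were named in neutrophil-like cells. Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) and Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452) belong to the interferon list. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929) and Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) were named for injury.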

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

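The 8 tests in this part were all laid down before the values they measure were seen, though after the patterns they address. What sets the results below apart is that the NP effect pointed one way at 2 dpi and the other way at 7 dpi, with counting intervals that leave out no change on both days. Shares were considered for classes with at least 100 cells in each library compared, and lists only in microglia-like, monocyte/macrophage-like, neutrophil-like, astrocyte-like and endothelial-like cells; other opposite signs are left out by this. With 1 library per group none of these differences was tested, and each value is the log2 ratio of NP over saline at 7 dpi minus that at 2 dpi.

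Among shares of cells, the difference was 1.90 for oligodendrocyte-lineage-like cells (ratios of 0.342 and 1.27), 1.87 for fibroblast-like cells (0.357 and 1.31), 0.948 for smooth muscle-like cells (0.690 and 1.33), 0.858 for dendritic cell-like cells (0.654 and 1.19) and 0.147 for microglia-like cells (0.934 and 1.03). The first of these is uncertain, since at 2 dpi the oligodendrocyte-lineage-like share was 1.27% and 2.65% in the probe barcode subsets of saline and 1.32% and 0.222% in those of NP, and its ratio was 0.141 to 0.753 over the alternatives. The microglia-like difference is lost outside the whole-library clusters, where the ratios were 1.07 and 1.066. At 2 dpi, 28.1% (saline) and 30.3% (NP) of smooth muscle-like cells lay in c53, led by Mcpt8, Prss34 and Fcer1a. This cluster correlated at 0.966 with its library and held 0 saline and 21 NP cells at 7 dpi. The other smooth muscle-like cluster, c33, held 2.30% (saline) and 1.54% (NP) of cells at 2 dpi. At 7 dpi it held 2.53% and 3.30%, so its shares also pointed opposite ways. In neutrophil-like cells the list medians differed by -1.13 for ageing and activation, -1.07 for inflammatory cytokines, -1.07 for chemokines, -0.60 for immediate early stress, -0.49 for interferon response, -0.36 for lipid handling, 0.52 for oxidative phosphorylation and 0.80 for granule genes. In c30 alone the sign was the same on both days for activation (0.34 and 0.10), inflammatory (0.28 and 0.04), stress (-0.09 and -0.04) and interferon (-0.19 and -0.59). For lipid handling (0.0024 [-0.03, 0.05], then 0.19) and oxidative phosphorylation (-0.08 [-0.12, 0.0019], then -0.18) the interval at 2 dpi held 0. For chemokines (0.19, then -0.07 [-0.16, 0.02]) and granule genes (0.09, then -0.05 [-0.18, 0.10]) the interval at 7 dpi held 0. In microglia-like cells they differed by 0.84 for interferon response and 0.10 for lipid handling (-0.07 and 0.03). In monocyte/macrophage-like cells they differed by 0.66 for interferon response, 0.26 for scavenger receptors, 0.14 for pro-repair genes, 0.11 for complement, 0.0875 for chemokines and 0.0566 for lipid handling; the last 3 were medians within 0.1 of 0 at both times, and pro-repair genes had 0.03 and 0.05 in the largest cluster of each day. With the mean of the cells' own CPM the interferon and pro-repair medians at 7 dpi were -0.01 and -0.03, below 0 as at 2 dpi, and with a class for each cell from its markers the chemokine median at 2 dpi was 0.16, above 0 as at 7 dpi.

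In astrocyte-like cells the differences were -1.98 for pan-reactive genes, -1.77 for fibrosis and matrix genes, -1.57 for A2-type genes, -0.72 for hypoxia and glycolysis and 1.01 for homeostasis, from 132 to 189 cells per library; with a class for each cell from its markers the A2-type median at 2 dpi was -0.16, below 0 as at 7 dpi. In endothelial-like cells they were 1.07 for proliferation, 0.29 for interferon response, 0.21 for hypoxia and glycolysis and -0.33 for immediate early stress. With the mean of the cells' own CPM the proliferation median at 7 dpi was -0.02, so the opposite sign is lost, and the share of the class in c3 was 24.9% in saline and 5.26% in NP at 2 dpi and 3.96% and 8.28% at 7 dpi.

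The higher activation and lower granule lists of neutrophil-like cells at 2 dpi may reflect fewer cells of the granule-gene clusters c26 and c28 in NP rather than a change within cells. In c30 alone the granule median was 0.0949 [0.08, 0.14] instead of -0.72, on the side of class make-up by the limit laid down. The clusters were formed from the same expression values, with c26 and c28 led by granule genes and c30 by Il1f9 and Il1b. A cell that changed under NP could fall in another cluster, so this value cannot tell make-up from a change within cells. The activation median in c30 was 0.34 [0.32, 0.36] instead of 1.00, between the limits of 0.2 and 0.5 laid down for and against make-up, so make-up and a response of the cells to NP cannot be told apart there. Free RNA is argued against: summed over the activation list, endothelial-like cells differed by -48.0 CPM and neutrophil-like cells by 16790 CPM, a share of -0.286%. Differences between the pooled animals remain open for both lists.

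The lower interferon list at 2 dpi was weighed against class make-up and free RNA. In microglia-like cells of c46 alone the median stayed at -0.52 [-0.63, -0.47], which argues against the shares of the clusters as its cause there. A differing mix of cells inside c46 is not covered by this value and was not tested. In monocyte/macrophage-like cells of c35 alone it was -0.18 [-0.22, -0.15] instead of -0.48, with an interval on both sides of the limit of -0.2, so make-up cannot be told apart from a change within cells. Free RNA stays open as well: the summed difference in pericyte-like cells was 15.9% of that in microglia-like cells, between the limits of 10% and 50%. An effect of NP on interferon signalling is a hypothesis that these libraries leave untested.

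The endothelial genes Fabp4, Aqp1 and Cd36, all higher in cluster c3, were lower with NP at 2 dpi and higher at 7 dpi. In the other main endothelial clusters, c0 and c1, the largest absolute log2 ratio was 0.27 at 7 dpi. These genes lay there at 0.581 to 7.01 CPM, so the 5 CPM added made their log2 ratios small. As plain folds in c0 and c1, Fabp4 was at 1.19-fold [0.854, 1.65], Aqp1 at 0.566-fold [0.333, 0.936] and Cd36 at 0.711-fold [0.596, 0.848]. Aqp1 and Cd36 were thus lower there, and the higher levels of the class on that day lay in c3. That day c3 was 8.28% of the class in NP and 3.96% in saline. The number of c3 cells alone does not account for Fabp4 at 6.70-fold and Cd36 at 4.66-fold, while Aqp1 rose less. At Leiden resolution 0.5, an endothelial-like cluster led by Gpihbp1, Aqp1 and Fabp4 held 0.00848% of saline and 0.257% of NP cells at 7 dpi. At 2 dpi it held 2.14% and 0.139%. Its share went the same way as these genes on both days, so make-up of the class stays open. Since Aqp1 and Fabp4 lead that cluster, its size cannot tell make-up from a change within cells. Levels within c3 were not tested. At 2 dpi the largest absolute log2 ratio in c0 and c1 was 1.66, with Fabp4 at -1.66, Aqp1 at -1.52 and Cd36 at -0.48. These genes went from at most 17.1 CPM in c0 and c1. For that day, make-up of the class, free RNA from c3 and a change within cells thus cannot be told apart.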

How the results depend on the processing

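The alternatives chosen only after results were seen were 5: the other naming fold, a correlation limit of 0.95, no correlation limit, shares outside the whole-library clusters, and the largest cluster of a class alone. No paired analysis was possible because each group is 1 library of pooled mice without animal labels, so leaving out replicates and splitting samples did not apply. Over 150 list medians with 1684 alternatives, 1209 stayed within the counting interval, 442 moved and 33 reversed. Over 132 named genes with 1170 the counts were 832, 336 and 2, and over 42 share ratios with 437 they were 335, 95 and 7. Wherever a result changed, the cause was not tested. Depth limits the classes with few cells, such as the 132 to 189 astrocyte-like cells, and thinning left out up to 17.5% of a library. In what follows, NP at a day means NP over saline, and values are log2 unless called ratios of shares.

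With members at 50 CPM or more, inflammatory medians were 0.157 (microglia-like, NP 7 dpi), 0.443 (monocyte/macrophage-like, NP 2 dpi), -0.23 (neutrophil-like, NP 7 dpi) and, reversed, 0.0854 (neutrophil-like, saline 7 over 2 dpi). Without the low-member filter they were 0.103 (microglia-like, NP 7 dpi), 0.443 and 0.0439 (monocyte/macrophage-like, NP 2 and 7 dpi), and 0.751 and -0.139 (neutrophil-like). With TMM factors, neutrophil-like inflammatory medians were 0.929 and -0.227 (NP 2 and 7 dpi) and, reversed, 0.122 (saline 7 over 2 dpi), and the fibroblast-like fibrosis median over laminectomy at 2 dpi reversed to -0.2002.

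With doublets kept, the neutrophil-like inflammatory median was -0.115 (NP 7 dpi), and ratios of the microglia-like share over laminectomy were 1.34 and 4.23 (saline 2 and 7 dpi). Reversed were neutrophil-like lipid handling (-0.0276, NP 2 dpi) and oligodendrocyte-lineage myelin and sterol genes (0.0292, NP 7 dpi).

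With the mean of the cells' own CPM, inflammatory medians were 0.284 (microglia-like, NP 2 dpi), 0.597 (monocyte/macrophage-like, NP 2 dpi), and 0.442 and -0.0427 (neutrophil-like, NP 2 and 7 dpi). Reversed in monocyte/macrophage-like cells at NP 7 dpi were the pro-repair (-0.0323), inflammatory (-0.0886) and interferon (-0.00543) lists, and in neutrophil-like cells at NP 2 dpi the interferon (-0.0905) and lipid handling (-0.0187) lists. Oligodendrocyte-lineage myelin and sterol genes reversed to 0.943 (NP 7 over 2 dpi) and 0.093 (NP 7 dpi), proliferation genes to 0.332 (the same class, NP 7 over 2 dpi) and -0.0244 (endothelial-like, NP 7 dpi).

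In the largest cluster alone, inflammatory medians were 0.206 (microglia-like, NP 7 dpi), 0.663 and 0.233 (monocyte/macrophage-like, NP 2 and 7 dpi), and 0.277 and, reversed, 0.0447 (neutrophil-like). At NP 2 dpi the pro-repair list of monocyte/macrophage-like cells (0.0314) and the immediate early stress (-0.0874), interferon (-0.194) and granule (0.0949) lists of neutrophil-like cells reversed. At NP 7 dpi the lipid handling (0.19), activation (0.105), granule (-0.0466) and oxidative phosphorylation (-0.183) lists of neutrophil-like cells and the homeostatic (0.0342) and proliferation (-0.0472) lists of microglia-like cells reversed.

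With a class for each cell from its marker score, inflammatory medians were 0.627 and 0.125 (monocyte/macrophage-like, NP 2 and 7 dpi) and 0.575 (neutrophil-like, NP 2 dpi). Reversed at NP 2 dpi were A2-type genes (-0.155, astrocyte-like), Prg2 (0.0569, neutrophil-like), chemokines (0.158, monocyte/macrophage-like), fibrosis genes (0.574, pericyte-like), and interferon (-0.0211) and oxidative phosphorylation (0.0572) in neutrophil-like cells. Also reversed were neutrophil-like lipid handling (0.549, NP 7 dpi), oligodendrocyte-lineage myelin and sterol genes (0.00227, NP 7 dpi, and -0.116, saline 7 over 2 dpi) and Ctsk in monocyte/macrophage-like cells (3.34, saline 2 dpi over laminectomy). Share ratios were 1.15 and 3.77 (microglia-like, saline 2 and 7 dpi over laminectomy), 1.15 (neutrophil-like, NP 2 dpi) and, reversed, 1.17 (monocyte/macrophage-like, NP 2 dpi).

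At Leiden resolutions 0.5 and 2 the neutrophil-like share ratio at NP 2 dpi was 1.099 and 1.09, and at 2 the microglia-like ratio was 3.403 (NP 7 over 2 dpi). Outside the whole-library clusters, microglia-like ratios were 3.05 (NP 7 over 2 dpi), 1.07 (NP 2 dpi, reversed), 1.066 (NP 7 dpi), 3.06 (saline 7 over 2 dpi) and 3.57 (saline 7 dpi over laminectomy). Monocyte/macrophage-like cells reversed to 1.06 and neutrophil-like cells were at 1.19, both at NP 2 dpi. Among leukocytes, microglia-like ratios were 2.92 (NP 7 over 2 dpi), 1.01 (NP 2 dpi, reversed), 0.572 (saline 2 dpi over laminectomy, reversed), 2.82 (saline 7 over 2 dpi) and 1.61 (saline 7 dpi over laminectomy), monocyte/macrophage-like cells were at 0.995 and neutrophil-like cells at 1.12 (NP 2 dpi), and the latter reversed to 0.97 (saline 2 dpi over laminectomy). After thinning to 1 depth, microglia-like ratios were 3.32 (NP 7 over 2 dpi), 1.36 (saline 2 dpi over laminectomy) and 2.98 (saline 7 over 2 dpi), the neutrophil-like ratio was 1.098 (NP 2 dpi), and the fibroblast-like ratio at NP 7 dpi was 0.0254. This last value, counted above as reversed, compares other cells: the only cluster named fibroblast after thinning held 86 saline and 2 NP cells at 7 dpi, and the cluster led by Dcn, Col1a1 and Lum, left unnamed, held 1.77% and 2.25%.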

Other observations

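None of the values in this part belongs to a test, and all were chosen after they were seen. Oligodendrocyte-lineage-like cells, made up of cluster c13 in the laminectomy and 7 dpi libraries and of c13, c14 and c25 at 2 dpi, had higher proliferation genes after injury, with medians of 3.43 [3.27, 3.62] at 2 dpi and 2.19 [2.07, 2.44] at 7 dpi over laminectomy and all 21 measured members at least 1.5-fold higher at both times. At 2 dpi these ran from Mcm5 at 3.82-fold and Pcna at 3.57-fold to Plk1 at 44.8-fold and Ube2c at 32.8-fold. Myelin and sterol genes were lower, at -1.60 [-1.71, -1.49] and -0.89 [-0.95, -0.81], with Mog at 0.0997-fold among the lowest and Fdps at 0.879-fold and Sqle, an enzyme of cholesterol synthesis, at 0.913-fold highest at 2 dpi. Compared with saline at 2 dpi, NP had higher myelin and sterol genes (0.90 [0.70, 1.01], from Idi1 at 0.820-fold and Fdps at 0.995-fold to Mag at 4.28-fold and Mbp at 5.80-fold) and lower proliferation genes (-1.21, from Ube2c at 0.264-fold and Plk1 at 0.272-fold to Tyms at 1.22-fold and Mcm3 at 1.42-fold). Of the class, c25 held 104 saline cells and 0 NP cells, and c14 held 249 and 140, and with each cell counted alike the myelin and sterol median was 0.07. With a correlation limit of 0.95 c14, which correlated at 0.961 with its library, is set aside and 61 NP cells remain, too few for a list value.

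Vascular and stromal cells also differed between the saline and laminectomy libraries. Proliferation genes of endothelial-like cells had a median of 1.70 [1.63, 1.78] at 2 dpi, from Pcna at 1.28-fold and Mcm6 at 1.43-fold to Ube2c at 25.1-fold and Top2a at 31.2-fold, and of 0.22 at 7 dpi. Their make-up differed too, with c3 at 0.670% of the class in laminectomy and 24.9% in saline at 2 dpi and c0 at 82.7% and 44.4%. Fibrosis and matrix genes of pericyte-like cells stood at 1.64 [1.47, 1.75] at 2 dpi, with 19 of 23 members at least 1.5-fold higher, with Col1a2 at 0.416-fold and Col1a1 at 0.465-fold lowest and Timp1 at 54.5-fold among the highest, and at 1.00 at 7 dpi, with 21.1%, 35.6% and 22.5% of the class in c32 in laminectomy and in saline at 2 and 7 dpi. Neutrophil-like cells had inflammatory medians of 3.19 and 2.59 and granule medians of -1.04 and -0.64 over laminectomy, where 63.1% and 32.2% of the class lay in the granule-gene clusters c28 and c26. In NP at 2 dpi their iron and heme list stood at 0.59 over saline, but at 0.30 in c30 alone, from Slc40a1, the iron exporter, at 0.778-fold and Tfrc at 0.789-fold to Slc7a11, a cystine transporter, at 2.02-fold and Srxn1, a sulfiredoxin of the oxidative stress response, at 2.17-fold.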
